A study of Mus musculus with 8 samples.

How the data were processed

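Total RNA was measured on 8 single-colour Affymetrix arrays, 1 array per sample, with biotin-labelled cRNA made from 5 µg of total RNA. The samples came from CT26 cells, an established mouse colon tumour epithelial line, and from RAW264 cells, an established mouse macrophage line, called RAW below. Each line was grown alone or in co-culture, where CT26 cells sat in a well and RAW cells in a transwell insert with a porous membrane, so that secreted molecules could pass but the cells did not touch. Per the labels' protocols, 10000 CT26 cells were seeded in 1.5 ml and 10000 RAW cells in 0.5 ml, and the inserts were moved into the wells 8 hours after seeding. CT26 cells were taken up with trypsin before lysis, whereas RAW cells were lysed on the insert, so the lines differ in harvest as well as in type. The experiment was performed on 2 occasions, which gave 4 groups of 2 arrays: CT26 alone, CT26 co-culture, RAW alone and RAW co-culture. The p-values of single genes therefore measure the spread between samples of 2 experiments.

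The deposited values are log2 expression values, and the authors made them with RMA in the affy package, per the submitters' processing notes. Versions and settings are not given in the sources used here. The table held 45101 probe sets, of which 64 were array controls and were left out. Array medians lay between 5.88 and 5.94 log2 units and the sorted columns differed by at most 0.117 log2 units, as after a quantile normalization over all arrays, which would remove any change in total RNA per cell. No pair of columns held identical values. RMA also compresses the lowest signals, so folds of genes near the background are understated, and the number of arrays limits the precision of every value.

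Probe sets were named from the platform annotation. Of the 45037 probe sets other than controls, 34945 had 1 gene symbol, 932 had several and 9160 were not listed there. Entrez identifiers of 34741 probe sets matched the RefSeq gene table of assembly GRCm38.p6, which was used for names alone, and 0 symbols changed. No coordinates are given, since no genome build is stated in the sources used here. A gene was represented by the probe set with 1 symbol and the highest mean over the 8 arrays, which gave 18193 genes. A gene was tested if its probe set lay above the 40th percentile of the array in both arrays of at least 1 group, a floor of 5.21 to 5.28 log2 units, which left 13196 genes.

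A linear model of the 4 group means was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3, with 4 residual degrees of freedom and moderated variances without a trend. The contrasts were co-culture minus alone in CT26, the same in RAW, the RAW effect minus the CT26 effect, and RAW alone minus CT26 alone. Tests were two-sided, with Benjamini-Hochberg adjustment over the 13196 genes and a threshold of 0.05 on the adjusted p. Errors of log2 changes are standard errors of the model, and group values are means with the SD of 2 arrays. Gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over 30 lists per contrast, and again with a correlation estimated for each list. At the preset correlation camera sets the genes of a list against all other genes, so its p-values do not measure the spread between samples. With an estimated correlation it also has the 4 degrees of freedom of the fit in place of those of the genes. A call lost that way is therefore not lost to correlation between genes alone. The ATF4 list in RAW had an estimated correlation of 0.00177, under the preset one, yet camera p rose from 3.79e-10 to 0.00214. No list call in the 3 co-culture contrasts held with an estimated correlation.

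The replicate numbers of the labels mark the 2 occasions on which the experiment was performed. Deviations of same-numbered arrays from their group means correlated across genes in every pair of groups, at 0.754 within CT26, 0.765 within RAW and 0.484 to 0.561 between the lines. The numbers were therefore taken to pair the samples. The main fit nonetheless had no block, as fixed before the data were examined, so its standard errors include the shift between experiments. Their median in the co-culture contrast of each line was 0.165 log2 units, against 0.0938 with a block per line. Fits with the experiment as a block, either shared by the lines (3 residual degrees of freedom) or separate in each line (2 residual degrees of freedom), were alternatives, and their values stand beside results that they change.

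The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The block per line for list tests and for single named genes was chosen after seeing the data. In each co-culture comparison the rule took the 8 largest rises and the 8 largest falls among genes past the threshold with the same sign in both experiments, filled up to 5 per direction by the largest moderated statistics, which are named as not past the threshold. For the difference between the lines it took up to 5 genes per direction past the threshold, and for the baseline the cell type markers. For each list described it took up to 4 members past the threshold or, with none, the 2 with the largest absolute change, and it always took Vdr, since the series title names the vitamin D receptor. Alternatives covered the filter on dim probe sets, the treatment of several probe sets per gene, the normalization, the variance model, the thresholds, the samples in the fit, the list test and leaving out each array in turn. A left-out array leaves its group with 1 array, which is then assumed to vary like the other groups.

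The gene test was tested on simulated data made from the real means and variances of the RAW comparison over 13196 genes, with 200 genes changed in each of 5 runs. Without the block, 73.6% of genes changed by 1 log2 unit and 98.4% of those changed by 2 log2 units were recovered, with a mean of 9.2 unchanged genes called. With a block per line on data that carried the real shifts between experiments, 100% were recovered at either size, with a mean of 18.2 unchanged genes called in RAW and 1.4 in CT26, where none was changed. In the simulated CT26 comparison over the same number of genes, a list of 38 genes raised by 0.5 log2 units was called in 10 of 10 runs and 1 of 300 unchanged lists was called. Genes were simulated as independent, which they are not in cells. The runs without the block and the list runs carried no shift between experiments, unlike the real data. Their rates therefore need not hold there and cannot be set beside those with a block.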

Results

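The data comprised log2 expression values of 13196 genes in CT26 colon tumour cells and RAW macrophages, grown alone or in a transwell co-culture without contact, with 2 arrays per group from 2 experiments. The design asks which transcripts change in each line when soluble molecules of the other line reach it.

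The lines were first compared when grown alone. All 24 tested macrophage markers were higher in RAW alone than in CT26 alone, with a median difference of 6.27 log2 units. Lyz2, which encodes lysozyme, stood at 15.26 ± 0.07 in RAW alone against 6.16 ± 0.08 in CT26 alone (log2, SD, n = 2), and Csf1r, the receptor of colony-stimulating factor 1, at 14.66 ± 0.02 against 5.59 ± 0.34. Of 29 tested mesenchymal and matrix markers, 23 were lower in RAW and 1 was higher, with a median of -3.86. The collagen gene Col1a2 had 13.55 ± 0.05 in CT26 alone and 6.42 ± 0.13 in RAW alone, and Sparc, a matrix glycoprotein, 12.65 ± 0.49 and 6.0 ± 0.15. Of 16 tested epithelial markers, 5 were lower in RAW and 2 higher. The epithelial markers Cdh1, Krt7, Cldn7, Ocln, Dsp, Vil1, Muc1 and Perp were too dim in every group, CT26 included, to be tested. Krt20, an intestinal keratin, and Tjp1, a tight junction protein, stood at 11.54 ± 0.02 and 11.64 ± 0.04 in CT26 alone against 4.88 ± 0.26 and 4.60 ± 0.11 in RAW alone, under the floor of the arrays. In total 4563 genes differed, 2244 of them higher in RAW, and 6978 did so with an experiment block shared by the lines and 7735 with a block per line. The macrophage list passed camera (adjusted p = 9.02e-23, and adjusted p = 0.0169 with an estimated correlation), as did the mesenchymal list (adjusted p = 1.71e-12, but adjusted p = 0.169 with an estimated correlation), whereas the epithelial list did not (adjusted p = 0.144). Of 6 lymphoid and 9 endothelial markers tested, 0 were called without a block (camera adjusted p = 0.912 and 0.969), and 1 endothelial marker was with a block per line.

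In co-cultured RAW cells 8 of 38 tested interferon-stimulated genes were called higher, while the call of the list was lost with an estimated correlation (adjusted p = 0.155). The genes named next are the largest rises among all called genes, and Ifi44l, H2-T24 and Irgm2 are not members of that list. Rtp4, an interferon-induced receptor chaperone rose by 4.77 ± 0.48 log2 units (SE), or 27.2-fold, from 7.68 ± 0.18 to 12.45 ± 0.19 (SD, n = 2). Usp18, a protease that removes ISG15 from proteins, rose by 4.51 ± 0.48, Ifi44l by 4.04 ± 0.15 and the transcription factor gene Irf7 by 3.74 ± 0.47. The non-classical MHC class I gene H2-T24 rose by 3.66 ± 0.23, the RNA sensor gene Dhx58 by 3.12 ± 0.33, the interferon-inducible GTPase gene Irgm2 by 2.49 ± 0.29 and Oasl1, of the oligoadenylate synthetase family, by 2.35 ± 0.21. Adjusted p lay between 0.000479 for Ifi44l and 0.0445 for Irf7, and each of these genes rose in both experiments. In RAW alone Ifi44l (4.89) and H2-T24 (5.22) lay under the floor of the arrays, so the size of their rise is not well measured. The choice of probe set mattered for size: averaged over all of its probe sets, the rise of Rtp4 was 2.96 log2 units. That average includes a dim probe set, with a mean of 4.61 over all arrays, which rose by 1.16. For Ifi44l, 1 of 3 probe sets, a dim one, changed by 0.096. Other probe sets of Dhx58 rose by 2.45 and, for a dim one, 0.61.

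The fall of single genes in co-cultured RAW cells was smaller. Olfml3, which encodes a secreted glycoprotein, fell by 2.67 ± 0.22 log2 units (SE), to 7.34 ± 0.19 (SD, n = 2). Vegfc, a lymphatic growth factor, was lower (-2.03 ± 0.20), as were the iron exporter gene Slc40a1 (-1.63 ± 0.17) and Fgf13 (-1.52 ± 0.10, from 8.55 to 7.03). Mfap3l had -1.38 ± 0.16, Serpinb1b, of the serine protease inhibitor family, -1.33 ± 0.11, the integrin gene Itgal -1.28 ± 0.15 and Ephx1, an epoxide hydrolase, -1.20 ± 0.14. Slc40a1, Mfap3l and Serpinb1b lay under the floor in RAW co-culture (4.90, 5.01 and 5.19), so the size of their fall is not well measured. Adjusted p lay between 0.00704 for Fgf13 and 0.0419 for Mfap3l, Itgal and Ephx1. With all probe sets of a gene averaged, Vegfc (adjusted p = 0.0576) and Mfap3l (adjusted p = 0.116) no longer passed. Another probe set of Fgf13, a dim one, changed by -0.47, and another of Itgal by -0.56.

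**Figure D1:**
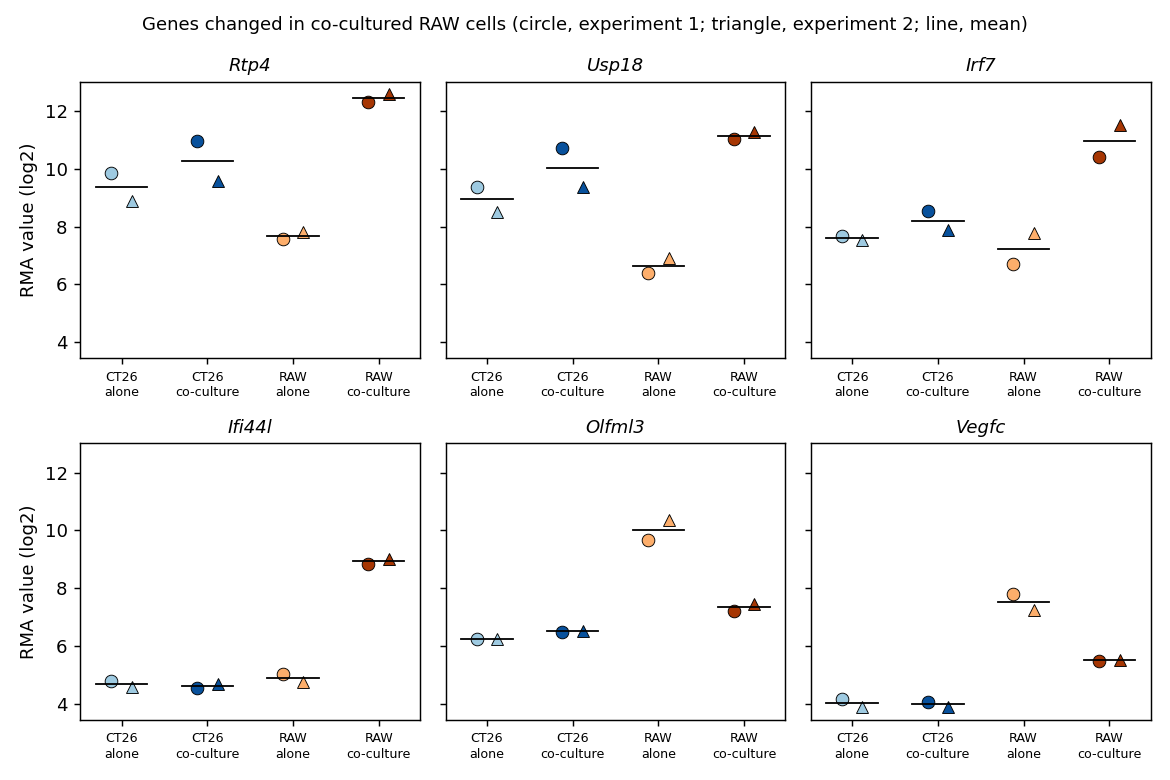
Log2 RMA values (y axis) of 6 genes in the 4 groups (x axis), with a circle for experiment 1, a triangle for experiment 2 and a line at the group mean. Rtp4, Usp18, Irf7 and Ifi44l were highest in RAW co-culture in both experiments, and Olfml3 and Vegfc were lower there than in RAW alone.

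Among 13196 genes, limma called 33 in RAW, 22 higher and 11 lower. A block shared by the lines called 146 genes, 67 higher and 79 lower, and a block per line called 470, 205 higher and 265 lower; each held all 33. Changes of more than 1 log2 unit in both experiments were seen for 58 genes that were higher and 36 that were lower. The count rests on few arrays: without a RAW alone array it was 2 (experiment 1) or 7 (experiment 2), without a RAW co-culture array 3 or 5, and without either CT26 alone array 3, while without either CT26 co-culture array it was 30. Leaving out an array leaves fewer samples, and leaving out a RAW array also breaks the pairing, so those counts mix the co-culture effect with the shift between experiments. A fit of the RAW arrays alone called 4.

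By list, the type I interferon-stimulated genes moved most in RAW. Of 38 tested members, 35 were higher in both experiments, 8 were called over all genes and 33 when adjusted over the list alone, and 30 were called with a block per line. The median change was 1.62 log2 units (camera adjusted p = 1.04e-55, and adjusted p = 0.155 with an estimated correlation). Among the 8 members called over all genes, Rtp4, Usp18, Irf7 and Dhx58 rose most. The list of interferon-gamma GTPases and antigen presentation genes had a median of 0.37, with 2 of 25 members called and 6 higher adjusted over the list alone, or 15 higher and 1 lower with a block per line (camera adjusted p = 9.98e-11, and adjusted p = 0.155 with an estimated correlation). Both called members, Irgm2 and Igtp (2.06 ± 0.25), are GTPases.

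The lists of amino-acid stress and antioxidant genes had medians of opposite sign in RAW, without a test of one against the other. Of 35 members of the ATF4 list, which holds amino-acid synthesis and transport genes, 29 were higher in both experiments, with a median of 0.31 (camera adjusted p = 3.79e-09, and adjusted p = 0.0642 with an estimated correlation), although 0 were called over all genes and 1 adjusted over the list alone. With a block per line 7 were called over all genes and, adjusted over the list alone, 20 higher and 1 lower. Stc2 had 1.11 ± 0.16 (adjusted p = 0.066) and Trib3 0.85 ± 0.54, and both passed with a block per line (adjusted p = 0.00936 and 0.0183). Of 27 members of the NRF2 list, which holds glutathione and detoxification genes, 22 were lower in both experiments, with a median of -0.35 (camera adjusted p = 1.28e-08, and adjusted p = 0.155 with an estimated correlation). None was called over all genes and 5 were when adjusted over the list alone, 4 of them lower. With a block per line 9 were called lower and 3 higher over all genes, and 15 lower and 3 higher adjusted over the list alone. Gclm, a subunit of glutathione synthesis, had -1.18 ± 0.45 (adjusted p = 0.875) and Cat, the catalase gene, -1.03 ± 0.27 (adjusted p = 0.454), and with a block per line adjusted p was 0.00113 and 0.00763.

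Smaller shifts passed in 7 other lists in RAW, and these also lost their call with an estimated correlation. Hypoxia targets had a median of 0.26 (adjusted p = 0.000111, and adjusted p = 0.509 with an estimated correlation), with Ndrg1 at 1.19 ± 0.38 and Adm, the adrenomedullin gene, at 1.16 ± 0.39. Cholesterol synthesis genes had 0.18 (adjusted p = 0.00117, and adjusted p = 0.509 with an estimated correlation), with Lss at 0.46 ± 0.21 and Insig1 at 0.43 ± 0.26. LXR and lipid export targets had 0.24 (adjusted p = 0.0326, and adjusted p = 0.509 with an estimated correlation), with the desaturase genes Scd1 at 1.66 ± 0.42 and Scd2 at 1.64 ± 0.23, and did not pass with a block per line (adjusted p = 0.124). Glycolysis enzymes had 0.18 (adjusted p = 0.0356, and adjusted p = 0.671 with an estimated correlation), with Slc16a3 at 0.68 ± 0.45 and Hk2 at 0.51 ± 0.17, and endoplasmic reticulum chaperones 0.095 (adjusted p = 0.00825, and adjusted p = 0.46 with an estimated correlation), with Herpud1 at 0.51 ± 0.26 and Manf at 0.38 ± 0.14. TGF-beta targets had -0.11 (adjusted p = 0.00767, and adjusted p = 0.509 with an estimated correlation), with Pmepa1 at -1.72 ± 0.47 and the integrin gene Itgav at -0.92 ± 0.21, and mesenchymal markers -0.13 (adjusted p = 0.00117, and adjusted p = 0.509 with an estimated correlation), where the caveolin gene Cav2 was called (-1.16 ± 0.12, adjusted p = 0.0257, and 0.0891 with its probe sets averaged). Of the genes in this paragraph, Ndrg1, Scd1, Scd2, Slc16a3, Hk2, Herpud1, Pmepa1 and Itgav passed with a block per line (adjusted p from 0.00184 to 0.0455). Other probe sets of Itgav changed by -0.83, -0.51 and, for the dimmest, 0.22 and 0.16. Several of these calls ended with an array left out, which breaks the pairing of the samples. Hypoxia ended without RAW co-culture 2 (adjusted p = 0.0552), cholesterol synthesis without RAW co-culture 1 (0.0832), TGF-beta without RAW co-culture 1 or RAW alone 2 (0.28 and 0.11). Glycolysis and chaperones ended without RAW alone 1 (0.894 and 0.16) or RAW co-culture 2 (0.813 and 0.327), and LXR targets ended without either CT26 alone array (0.0593 each), RAW alone 1 (0.517), RAW co-culture 1 (0.0844) or RAW co-culture 2 (0.0552).

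The other 19 lists did not pass in RAW, with adjusted p from 0.0812 for ribosome biogenesis to 0.994. With a block per line, ribosome biogenesis (median 0.094, adjusted p = 0.0157) and DNA replication (0.095, adjusted p = 0.0426) did, but not with an estimated correlation as well (adjusted p = 0.747 and 0.554). Macrophage markers had a median of -0.027 (adjusted p = 0.495); in that list the Fc receptor gene Fcgr1 had 1.77 ± 0.24 (adjusted p = 0.0585) and Adgre1 -0.75 ± 0.30, and both passed with a block per line (adjusted p = 0.00722 and 0.0306). The NF-kB list had a median of 0.078 (adjusted p = 0.43), with the chemokine genes Ccl7 at 1.73 ± 0.37 and Ccl2 at 1.54 ± 0.66, which passed with a block per line (adjusted p = 0.00983 and 0.0265). In the list of alternative activation (adjusted p = 0.0844), Il10, under the floor in co-culture, had -1.51 ± 0.21 (adjusted p = 0.0585, and 0.0016 with a block per line) and Clec7a -0.96 ± 0.40. Among osteoclast genes, a list that did not pass without a block (median -0.29, adjusted p = 0.238) and passed as lower with a block per line (adjusted p = 0.0477, and adjusted p = 0.39 with an estimated correlation as well), the carbonic anhydrase gene Car2 rose by 2.14 ± 0.22 (adjusted p = 0.0257). Vdr stood at 5.99 ± 0.12 in RAW alone and 5.94 ± 0.14 in co-culture, a change of -0.05 ± 0.13 within the spread of the arrays (adjusted p = 1.00).

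No gene passed the threshold in co-cultured CT26 cells, with or without the block. With limma, 107 of 13196 genes had an unadjusted p under 0.05 without a block, 356 with a shared block and 752 with a block per line, and the smallest adjusted p was 1.00, 0.713 and 0.139. The largest moderated statistics, none past the threshold, belonged among higher values to Tnfrsf9, a receptor of the TNF family (0.94 ± 0.18), Gbp2, an interferon-inducible GTPase (0.84 ± 0.19), Btbd17 (0.47 ± 0.12), Ddx60, a helicase (0.97 ± 0.27), and 1500002C15Rik (0.52 ± 0.15). Among lower values they belonged to Rnf130 (-0.99 ± 0.14), Akr1c14 (-0.80 ± 0.14), Cyp39a1 (-0.45 ± 0.12), Styk1 (-0.48 ± 0.13) and Asrgl1 (-0.54 ± 0.15), as log2 change ± SE. Averaged over all probe sets of the gene, Asrgl1 had -0.0062, with another bright probe set at 0.32, Rnf130 -0.27 and Tnfrsf9 0.69. Another probe set of Btbd17, a dim one, had -0.13. Gbp2 in CT26 alone and Rnf130 in CT26 co-culture lay under the floor. No gene moved by more than 1 log2 unit in both experiments, and the changes of the experiments correlated across genes at r = 0.14, against 0.61 in RAW, where genes are not independent replicates. Vdr stood at 6.32 ± 0.02 in CT26 alone and 6.41 ± 0.09 in co-culture, a change of 0.09 ± 0.13. Another probe set of Vdr, near the floor with a mean of 5.23 over all arrays, changed by 0.35 in CT26.

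As a list, interferon-stimulated genes were higher in co-cultured CT26 cells. Of 38 tested members, 33 were higher and 0 lower in both experiments, with a median of 0.44 log2 units (camera adjusted p = 9.67e-24, and adjusted p = 0.542 with an estimated correlation), and 0 were called over all genes or adjusted over the list alone. With a block per line 0 were called over all genes and 27 adjusted over the list alone, as were 7 members of the interferon-gamma list, 6 hypoxia targets, 4 members of the NF-kB list and 1 glycolysis enzyme, all higher. Called lower in the same way were 2 TGF-beta targets and 1 member each of the osteoclast, immediate-early and Wnt lists. Usp18 had 1.10 ± 0.48 and Xaf1 1.01 ± 0.51. The interferon-gamma list had a median of 0.22 (adjusted p = 6.52e-09, and adjusted p = 0.447 with an estimated correlation), with Gbp2 at 0.84 ± 0.19 and Gbp3 at 0.71 ± 0.32. Hypoxia targets had 0.25 (adjusted p = 7.74e-08, and adjusted p = 0.542 with an estimated correlation), with Ankrd37 at 0.80 ± 0.74 and Ndrg1 at 0.70 ± 0.38, and glycolysis enzymes 0.13 (adjusted p = 0.00128, and adjusted p = 0.647 with an estimated correlation), with Eno2 at 0.68 ± 0.68 and Slc16a3 at 0.55 ± 0.45. The NF-kB list had 0.10 (adjusted p = 0.0043, and adjusted p = 0.447 with an estimated correlation), with Nfkbie at 0.84 ± 0.34 and Relb at 0.74 ± 0.39, and DNA replication genes -0.071 (adjusted p = 0.0196, and adjusted p = 0.647 with an estimated correlation), with Gins3 at -0.24 ± 0.21 and Ccne2 at -0.21 ± 0.27. Within experiments the interferon-stimulated genes had medians of 0.56 and 0.28 and the hypoxia targets, 25 of 32 of them higher in both and 2 lower in both, 0.39 and 0.11. Leaving out an array breaks the pairing of the samples, so the values that follow mix the co-culture effect with the shift between experiments. Without CT26 co-culture 1 the interferon-gamma list alone passed (adjusted p = 0.0218) and the medians of interferon-stimulated genes and hypoxia targets were 0.14 (adjusted p = 0.392) and 0.016 (adjusted p = 0.786), with Ankrd37 at -0.36 and Eno2 at -0.24. Without CT26 alone 2 both interferon lists passed and no other. DNA replication also ended without CT26 alone 1 (adjusted p = 0.233) and after cyclic loess normalization (adjusted p = 0.146), and Ccne2 had 0.052 without CT26 co-culture 2.

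With a block, whether shared or per line, 10 lists passed in CT26 in place of 6. The added ones were ribosome biogenesis, mitosis, ATF4 and cholesterol synthesis (adjusted p = 0.0188, 0.032, 0.00718 and 0.027 with a block per line), whose medians were -0.059, -0.051, 0.051 and 0.076. With an estimated correlation as well, adjusted p was 0.70 for ribosome biogenesis and 0.676 for each of the others. The other lists had adjusted p from 0.116 to 0.971 without a block, apart from ribosome biogenesis (0.054), ATF4 (0.0577) and mitosis (0.0607). Macrophage markers, which the other line expresses, had a median of -0.028 in CT26 cells (adjusted p = 0.478), with Lcp1, under the floor, at -0.38 ± 0.17 and Spi1 at -0.37 ± 0.36.

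**Figure D2:**
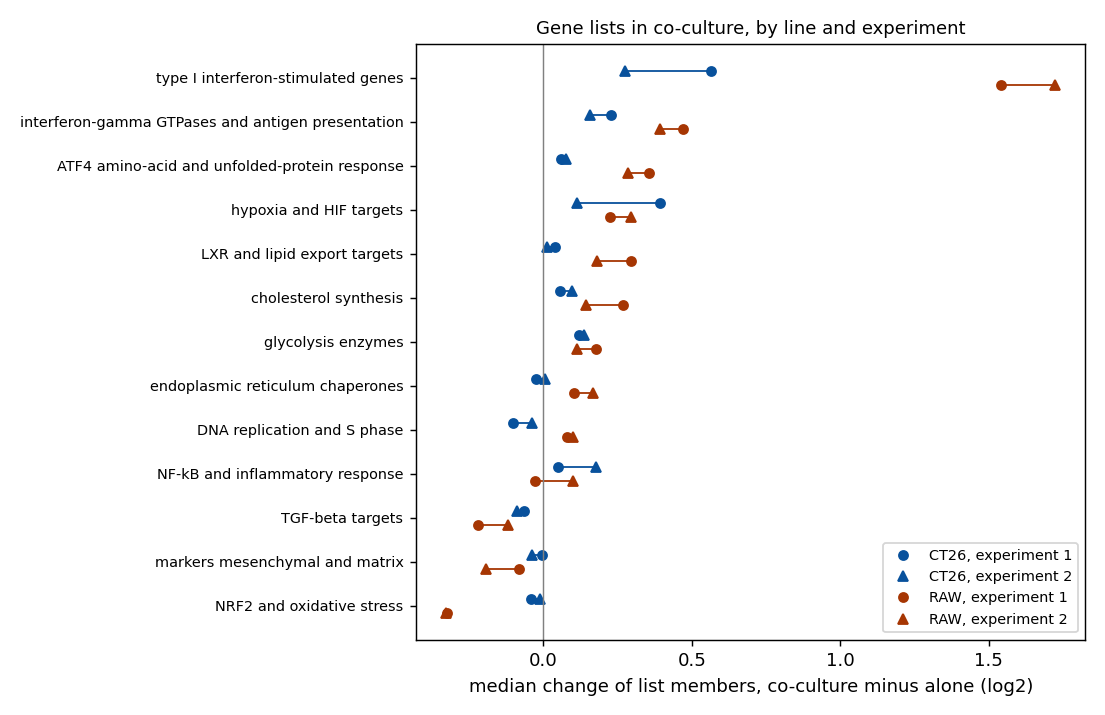
Median log2 change of list members, co-culture minus alone (x axis), in CT26 (blue) and RAW (red) for experiment 1 (circles) and experiment 2 (triangles), for the 13 lists that passed camera in either line (y axis). The interferon-stimulated genes lie at 1.54 and 1.72 in RAW and at 0.56 and 0.28 in CT26.

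The response of RAW was set against that of CT26 by a test of the difference. Ifi44l was the gene called, with a RAW effect 4.10 ± 0.21 log2 units above the CT26 effect (adjusted p = 0.00446). It lay under the floor of the arrays in CT26 alone (4.67), CT26 co-culture (4.61) and RAW alone (4.89), so a change in CT26 may have been missed and the size of the difference is not well measured. With the experiment as a block, 11 genes were called when it was shared and 98 when it was per line. Rtp4 and Usp18 had differences of 3.85 ± 0.68 and 3.42 ± 0.68, which passed with a block per line (adjusted p = 0.000529 and 0.00113). Without CT26 alone 1 or CT26 co-culture 1 the call of Ifi44l ended (adjusted p = 0.0597 and 0.0566), while without RAW alone 1 or RAW co-culture 1 the count was 2. By list, 8 of 30 differed without a block, 11 with a shared block and 12 with a block per line, and none kept the call with an estimated correlation. The lists added were TGF-beta targets, cholesterol synthesis, alternative activation and, per line alone, osteoclast genes (adjusted p = 0.0146, 0.0401, 0.0401 and 0.0442 with a block per line, and 0.492, 0.615, 0.429 and 0.429 with an estimated correlation as well). The interferon-stimulated genes had a median difference of 1.13 (adjusted p = 3.42e-34, and adjusted p = 0.444 with an estimated correlation), the NRF2 list -0.23 (adjusted p = 3.01e-05, and adjusted p = 0.444 with an estimated correlation) and the ATF4 list 0.23 (adjusted p = 0.000104, and adjusted p = 0.232 with an estimated correlation). Members of these were Gclm at -1.26 ± 0.64, the heme oxygenase gene Hmox1 at -1.19 ± 0.43, Stc2 at 1.26 ± 0.23 and Trib3 at 0.80 ± 0.76.

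Across all 13196 genes the co-culture effects of the lines correlated weakly, at r = 0.20 and a Spearman rho of 0.13, where genes are not independent replicates. By experiment rho was 0.151 for experiment 1 of both lines, 0.0896 for experiment 2 of both, 0.00385 for CT26 experiment 1 with RAW experiment 2 and 0.0875 for the reverse. Of the 22 genes called higher in RAW, 12 were higher in both CT26 experiments, or 54.5%, against 23.8% of all genes tested, and their median change in CT26 was 0.15 log2 units against 2.13 in RAW. The 11 genes called lower in RAW had a median of -0.043 in CT26 against -1.33 in RAW, and 2 of them were higher in both CT26 experiments. The effects of the lines correlated at r = 0.58 among the 22 and at r = -0.58 among the 11. No overlap of called genes could be counted, since 0 were called in CT26.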

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

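The tests in this part were chosen before their results were seen, except for the values over the 33 interferon-stimulated genes, the level of the CT26 markers beside them, the share of CT26 RNA needed and the ranks within arrays. The results listed here are those whose co-culture effect differed between the lines by a test of the difference without a block. With a block, TGF-beta targets, cholesterol synthesis, alternative activation and, per line alone, osteoclast genes passed too, but not with an estimated correlation as well. The gene Ifi44l had a RAW effect 4.10 log2 units above the CT26 effect, a size not well measured since the gene lay under the floor of the arrays in CT26 and in RAW alone. The median differences, RAW effect minus CT26 effect, were 1.13 log2 units for interferon-stimulated genes, 0.19 for interferon-gamma GTPases and antigen presentation (adjusted p = 0.00188, with Irgm1 at 1.96 ± 0.44 and Irgm2 at 1.82 ± 0.42, adjusted p = 0.568 with an estimated correlation, and 0.285 without RAW alone 1 and 0.212 without RAW co-culture 2), 0.23 for the ATF4 list and -0.23 for the NRF2 list. They were 0.10 for endoplasmic reticulum chaperones (adjusted p = 0.00643, and adjusted p = 0.524 with an estimated correlation), 0.12 for DNA replication (adjusted p = 0.00294, and adjusted p = 0.613 with an estimated correlation) and 0.17 for ribosome biogenesis (adjusted p = 0.00538, and adjusted p = 0.643 with an estimated correlation). Mesenchymal markers differed by -0.14 (adjusted p = 0.00124, with Cav1 at -2.0 ± 0.39 and Cav2 at -1.10 ± 0.17, and adjusted p = 0.568 with an estimated correlation), a call that ended without CT26 alone 1 (median 0.028, adjusted p = 0.281) and without CT26 co-culture 2 (adjusted p = 0.314). Chaperones also ended without CT26 alone 1, RAW alone 1, CT26 co-culture 2 or RAW co-culture 2 (adjusted p from 0.0893 to 0.213), ribosome biogenesis without CT26 co-culture 1, CT26 alone 2 or RAW co-culture 2 (0.0909 to 0.615), and DNA replication without RAW co-culture 1 or RAW alone 2 (0.382 and 0.663). With 2 arrays per group no array could be tested as lying apart from its group.

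The rise of interferon-stimulated genes in RAW co-culture was weighed against RNA of CT26 cells in those samples, the normalization and a single deviating experiment. Mixing cannot lift a gene above its source, yet 25 of the 33 members called when adjusted over the list alone stood above CT26 co-culture in RAW co-culture, 17 of them by more than 1 log2 unit, as did 75% of the 8 called over all genes, where the smallest gap was -0.99. For the 8 of the 33 that were not above it the exclusion rests on markers, since a median CT26 share of 41.1% would be needed, which would lift 17 CT26 markers by a median of 4.85 log2 units, whereas their median change was -0.0912 (median levels 5.11 and 5.09). The median rank of the list was at least 28.4 percentiles higher in RAW co-culture than in RAW alone, against at most 3.99 between arrays of a group. An increasing map of each array keeps the order of its genes, so such a map alone would not change these ranks. With sorted columns nearly alike, however, a rise in value is also a rise in rank. The ranks therefore restate the rise, and other steps of the normalization were not tested, so the normalization is not decided. The median rise of the list was at least 1.54 log2 units in each experiment. The mixing values and the 2 experiments argue against CT26 RNA and a single deviating experiment. A response of RAW cells to soluble molecules of CT26 cells is the hypothesis the design names, found and tested on the same data. Other differences of the co-culture, such as the use of medium by 2 cell populations, were not tested.

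The smaller rise of these genes in CT26 co-culture was weighed against RNA of RAW cells. A median RAW share of 14.0% would be needed over 22 members, which would lift 22 macrophage markers by a median of 3.86 log2 units, whereas they changed by -0.0654 (bootstrap standard error 0.0758). Single markers varied, with Lyz2 at 0.021 and Ctss, under the floor in CT26, at 0.36. The genes that fell in RAW co-culture were weighed against RNA of CT26 cells in the RAW alone samples. The 17 CT26 markers changed by a median of -0.0912 in RAW co-culture (bootstrap standard error 0.0819), above the -0.3 fixed as the limit for such a source. These markers were chosen as low in RAW alone, at a median of 5.11 under the floor of the arrays, and could hardly fall further. Their change therefore cannot decide the question. The whole mesenchymal list, mostly higher in CT26 alone, had a median of -0.13. The 17 CT26 markers stood at a median of 11.54 in CT26 alone against 5.11 in RAW alone, which leaves room for a small share of CT26 RNA only. Of the 11 called genes, 7 were higher in RAW alone than in CT26 alone. For the others the share needed was not computed, so CT26 RNA remains open for them.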

How the results depend on the processing

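The alternatives were planned, apart from list tests with a block per line and named genes with a block per line, which were chosen after seeing the data. The count of 0 genes in CT26 held under every alternative, and the 33 in RAW became 146 with a replicate block shared by the lines, 470 with a replicate block per line, 62 at adjusted p under 0.1, 4 with the compared groups alone and 2 to 30 with an array left out. The 1 gene of the difference between the lines became 11 and 98 with the blocks, 3 with every probe set on its own, after quantile normalization within lines or at adjusted p under 0.1, 4 with trended and robust variance and 0 to 2 with an array left out. The 4563 of the baseline became 6978 with a shared block, 7735 with a block per line and 7896 with every probe set on its own, which tests 23972 probe sets. Lists past the threshold were 6 in CT26, 11 in RAW and 8 for the difference; each fell to 0 with an estimated correlation, also with a block per line, and to 0, 1 and 0 with fry, where the ATF4 list in RAW remained. With the shared block and the block per line 10 and 10 lists passed in CT26, 12 and 13 in RAW and 11 and 12 for the difference. With an array left out, 1 to 8, 10 to 11 and 6 to 12 passed. The correlation of the lines, 0.20, was 0.117 for experiment 2 of both, 0.118 for CT26 experiment 1 with RAW experiment 2 and 0.118 for CT26 experiment 2 with RAW experiment 1. Under the 2 other normalizations the median effect over all genes moved by less than 0.1 log2 units. Both were applied to values whose arrays already had nearly the same distribution, so this could hardly have come out otherwise. Signs turned with an array left out: in CT26, Ankrd37 had -0.36 and Eno2 -0.24 without CT26 co-culture 1, against 1.96 and 1.59 without CT26 co-culture 2, and Ccne2 -0.48 and 0.0516. Vdr in RAW had 0.0374 without RAW alone 1 and 0.0522 without RAW co-culture 2, against -0.15 without RAW co-culture 1. Among named genes, a block per line brought 25 past the threshold and ended no call, and averaging probe sets ended 3. Leaving out an array leaves fewer samples and breaks the pairing; the cause of the other changes was not tested. Genes near the floor of the arrays are limited by signal over background.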

Other observations

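The baseline of the lines held list differences outside the cell type markers. Lysosome genes were higher in RAW alone than in CT26 alone by a median of 1.01 log2 units, with 15 of 29 called higher and 1 lower (camera adjusted p = 1.74e-06, and adjusted p = 0.347 with an estimated correlation). Osteoclast genes were higher by 2.12 (adjusted p = 0.00467, and adjusted p = 0.245 with an estimated correlation) and endoplasmic reticulum chaperones by 0.42 (adjusted p = 0.00179, and adjusted p = 0.245 with an estimated correlation). The ATF4 list was lower in RAW by a median of -1.24, with 24 of 35 members called lower and 2 higher (adjusted p = 2.28e-06, and adjusted p = 0.0676 with an estimated correlation). Growth factors and their receptors were lower in RAW by -1.52, with 18 of 31 called lower and 4 higher (adjusted p = 5.35e-05, and adjusted p = 0.0715 with an estimated correlation). Csf1, the ligand of the macrophage receptor Csf1r and chosen here after its values were seen, stood at 11.48 ± 0.48 in CT26 alone and 5.89 ± 0.29 in RAW alone (log2, SD, n = 2; adjusted p = 1.02e-05).

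Before co-culture, interferon-stimulated genes had a median difference, RAW minus CT26, of -0.42 log2 units, which was not past the threshold without a block (adjusted p = 0.208, and adjusted p = 0.959 with an estimated correlation) or with either block (adjusted p = 0.295 shared and 0.231 per line). Single members differed in both directions, with 11 of 38 called lower in RAW alone and 6 higher, or 20 lower and 10 higher with a block per line. RAW alone was above CT26 alone for 14 of 38 members, and RAW co-culture above CT26 co-culture for 26.

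One hypothesis, with its test fixed before the result was seen, is that CT26 cells may supply an interferon whose transcript the array can measure. Of 10 interferon genes with a probe set, 3 lay above the floor in both CT26 alone arrays, and 1, Ifnz, was also at least 1 log2 unit higher there than in RAW alone, at 7.26 ± 0.14 against 6.03 ± 0.25 (SD, n = 2; adjusted p = 0.00194), so the requirement was met by 1 gene with 1 probe set, whose specificity was not tested here. Ifnb1 had 5.24 in CT26 alone and 5.16 in RAW alone. The values measure transcript, not secreted protein, and Ifnz in CT26 changed by 0.08 ± 0.18 in co-culture, so the source of the signal remains open.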
